A study of Mus musculus with 18 samples.

How the data were processed

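RNA from 18 samples of mouse motor neurons or spinal cord tissue was measured on Affymetrix mouse expression arrays, 1 array per sample, after a T7-based linear amplification, per the labels. The samples fall into 6 groups of 3: ventral spinal cord tissue, motor neurons of the spinal cord and motor neurons of the facial nucleus, each from wildtype and from SOD1 mutant mice. The labels give no protocol for picking the motor neurons, no SOD1 allele, no sex and no batch, and the D60 in every title is not explained there. They also do not tie samples to animals, so all p-values measure only the spread between these samples, which may be partly technical.

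The authors deposited 1 table of linear intensities with 1 value for each of 45101 probe sets on each array. How the scanner images became these intensities is not stated by the authors. In the deposited values the mean after trimming 2% of the probe sets at each end was 2500 on every array, so each array had been scaled to one target. The distributions had not been matched: the median intensity was between 533 and 583 on the tissue arrays and between 286 and 341 on the motor neuron arrays. Arrays have no read depth, and the precision of each value is limited by the number of arrays, 3 per group.

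The intensities were converted to log2(intensity + 16) and quantile normalized over the 18 arrays, because the quartiles of the arrays differed by more than 0.1 on the log2 scale. Differences are therefore on the log2(value + 16) scale, which understates changes of dim genes. Probe sets were named from the platform annotation and the reference table of mouse genes: 34958 had 1 gene symbol, 932 had several, 9211 had none, and 64 were Affymetrix controls. Of those with 1 symbol, 34754 had a gene identifier in the reference table. Each gene was represented by its single-symbol probe set with the highest mean over the 18 arrays, which gave 18193 genes. In each fit, genes with a mean under the 40th percentile of all genes were left out, and 10916 genes were tested. Values below 8.79, the 40th percentile over the 18 arrays, are close to background, so a difference from such a level is given as a log2 difference with no fold.

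Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment at 0.05 over the tested genes. SE stands for the standard error of the log2 difference from limma, with n = 3 arrays in each group throughout. Genotypes were compared in each of the 3 kinds of sample. Both differences between genotype effects, spinal motor neurons against tissue and spinal against facial motor neurons, were tested as interaction contrasts over 12 arrays. Wildtype spinal motor neurons were compared with wildtype tissue and with wildtype facial motor neurons. Each comparison used the arrays of its own groups, since amplified cells and tissue were not assumed to share one spread.

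From 42 gene lists of cell types and pathways, 39 were tested with camera from limma at a preset correlation between genes of 0.01, in each comparison where at least 4 members were tested. Benjamini-Hochberg adjustment ran over the lists of a comparison. Of 787 list entries, 679 matched a gene on the arrays, 2 of them through an older symbol. Sex-linked and blood genes were described and not tested, the list of Schwann cell genes had too few members to be tested, and no blood gene passed the brightness filter in any comparison. For each list the count of members past the threshold is given over all tested genes and adjusted over the list alone. Each list was also tested with a correlation estimated from the data.

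The named genes are Sod1, up to 10 genes with the largest difference per direction among those past the threshold whose groups did not overlap, and the 4 members with the smallest p of each list that passed. A direction with fewer than 5 genes was filled to 5 with the smallest p. Interactions name the 5 smallest p per direction. Predicted genes without a symbol of their own were counted but not named. The groups, tests, lists, naming rule and alternatives were chosen before the data were examined, apart from the actin ratio as a covariate, both replicate 1 wildtype motor neuron arrays left out together, and the tests that the closing section names as later choices.

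The alternatives were the deposited values shifted to a common median, quantile normalization of part of the arrays, a pseudocount of 1 or 64, no filter or a filter at the 60th percentile, every probe set tested, no mean-variance trend, all 18 arrays in one fit, array weights, the replicate number as a block, and each array left out in turn. The log2 ratio of 3' to 5' actin control probe sets was added as a covariate in all 7 comparisons after the data were seen. It measures how far the amplified RNA reaches to the 5' end. Loss in the source RNA and loss in the amplification are not told apart by it, and RNA quality below stands for both. Between tissue and picked cells this ratio follows the kind of sample, so in those comparisons it and the kind can hardly be separated.

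The procedure was tested on simulated data with the spread of the real arrays and known changes among 10916 genes. In the spinal motor neuron comparison it recovered 30.2% of genes changed 2-fold and 76.8% of genes changed 4-fold, in tissue 85.7% and 100%, and in facial motor neurons 40.4% and 82.1%. The share of unchanged genes among those called was 5.36% in spinal motor neurons, 3.98% in tissue and 1.61% in facial motor neurons. In the comparisons that take more than 1 kind of sample into a fit it was 12.9% in the interaction with tissue, 9.30% in the interaction with facial motor neurons, 13.0% between motor neurons and tissue, and 8.66% between both kinds of motor neurons. In these 4 and in spinal motor neurons it was above the nominal level of 0.05, in spinal motor neurons by 6 of 112 called genes. Each comparison was simulated in 1 draw with few changed genes, such as 96 by 2-fold and 93 by 4-fold between motor neurons and tissue. There and between both kinds of motor neurons the simulated groups otherwise had equal levels. The share of 13.0% therefore does not carry over to the real comparison with tissue, where 6404 genes passed. None of the 38 unchanged lists was called. The simulated genes varied independently of each other, so this does not show how the list test behaves where genes vary together. With the real arrays split into other groups of 3, a median of 6 lists passed in spinal motor neurons, 3 in tissue and 3 in facial motor neurons. It was 9 between motor neurons and tissue and 5 between both kinds of motor neurons. Figures were drawn with matplotlib. The main fits left out control probe sets, probe sets without exactly 1 gene symbol, the dimmer probe sets of each gene and genes under the filter.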

Results

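Gene expression was measured in 18 mouse samples of 6 groups. These were ventral spinal cord tissue, motor neurons of the spinal cord and motor neurons of the facial nucleus, a motor nucleus of the brainstem, each from 3 wildtype and 3 SOD1 mutant samples. Mutations of SOD1, the gene of a cytosolic superoxide dismutase, are a known cause of amyotrophic lateral sclerosis. The design asks what differs between genotypes in motor neurons of either site and in the tissue around the spinal ones. Arrays of one group correlated with the others of their group at a mean r across genes of 0.971 to 0.976 in tissue and 0.915 to 0.944 in motor neurons. The lowest was wildtype spinal motor neurons replicate 1. The 3' to 5' ratio of the actin control probe sets was 1.63 ± 0.06 (SD, n = 3) in wildtype tissue and 1.64 ± 0.12 in mutant tissue. In spinal motor neurons it was 46.5 ± 9.06 in wildtype and 30.7 ± 7.36 in mutant samples, and in facial motor neurons 67.6 ± 7.44 and 39.8 ± 17.0. The same ratio of the Gapdh control probe sets was 32.4 ± 15.7 in wildtype and 21.1 ± 0.58 in mutant spinal motor neurons. In facial motor neurons the Gapdh ratio was 23.6 ± 3.52 and 18.4 ± 3.60. Xist, the RNA of the inactive X chromosome, was between 12.85 and 14.60 on the log2 scale on all 18 arrays. The 3 genes of the Y chromosome were at or below 8.60, under the 40th percentile of genes.

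Sod1 was among the brightest genes in every group and measured higher in mutants in the 3 kinds of sample. Its mean log2 intensity was 16.10 ± 0.08 (SD, n = 3) in wildtype and 16.49 ± 0.10 in mutant tissue, where it rose (log2 difference 0.38, SE 0.07, adjusted p = 0.0395). It was 16.40 ± 0.05 and 16.85 ± 0.02 in spinal motor neurons (log2 difference 0.46, adjusted p = 0.141). In facial motor neurons it was 16.51 ± 0.06 and 16.75 ± 0.09 (0.24, adjusted p = 0.162), and it did not pass the test in either kind of motor neuron. A second bright probe set gave 0.15 in tissue, 0.12 in spinal and 0.06 in facial motor neurons, and a dimmer one gave -0.44, -1.66 and -0.95. Another dim one gave -0.01, 0.16 and -0.44. The labels do not say whether the mutant gene is a mouse or a foreign one, so these probe sets check the genotype labels only in part.

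In spinal motor neuron samples of SOD1 mutants, 6 genes rose that are known from astrocytes, immune cells or lysosomes. Gfap, the intermediate filament of astrocytes, rose from a log2 level of 11.10 ± 0.27 (SD, n = 3) to 13.95 ± 0.36, which is 7.20-fold (log2 difference 2.85, SE 0.24, adjusted p = 0.00154). Laptm5, a lysosomal membrane protein of blood and immune cells, rose 6.17-fold (2.63, SE 0.24, adjusted p = 0.00154). Ctss and Ctsz, both lysosomal cathepsins, rose 3.99-fold (SE 0.26 on the log2 scale, adjusted p = 0.0206) and 2.83-fold (SE 0.21, adjusted p = 0.0309). The class I antigen-presenting gene H2-K1 rose by 1.99 (SE 0.26, adjusted p = 0.0206) and Grn, which encodes progranulin, by 1.33 (SE 0.19, adjusted p = 0.0379). Psmd6, a subunit of the regulatory particle of the proteasome, fell by 1.13 (SE 0.14, adjusted p = 0.0206).

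Among the gene lists, microglia markers rose together in mutant spinal motor neurons. All 12 tested members were higher, with a median log2 difference of 1.99, 2 past the threshold over all genes and 9 adjusted over the list alone (adjusted p = 4.11e-15; adjusted p = 0.237 with an estimated correlation). Csf1r, the growth factor receptor of microglia, was at 1.97 (adjusted p = 0.0685), and C1qc, a complement gene, at 2.25 (adjusted p = 0.194). Interferon and antigen presentation genes were higher in 9 of 9, with a median of 1.48, 1 past the threshold and 7 adjusted over the list alone (adjusted p = 3.59e-11; adjusted p = 0.0727 with an estimated correlation). B2m, the light chain of class I molecules, was at 0.91 (adjusted p = 0.106). Genes of microglial activation were higher in 12 of 12 with a mean log2 difference of 1.55, 1 past the threshold and 8 adjusted over the list alone (adjusted p = 5.71e-11; adjusted p = 0.0727 with an estimated correlation). The lymphocyte and microglia surface gene Cd52 was at 4.02 (adjusted p = 0.109), with a wildtype level close to background. Reactive astrocyte genes were higher in 5 of 5, median 0.76, 1 past the threshold and 4 adjusted over the list alone (adjusted p = 2.1e-06; adjusted p = 0.0727 with an estimated correlation). In these samples the actin ratio was 46.5 ± 9.06 in wildtype and 30.7 ± 7.36 in mutants (SD, n = 3).

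Genes that respond to axon injury also rose as a list in mutant spinal motor neurons. Of these, 14 of 16 were higher with a median of 0.74, none past the threshold over all genes and 8 adjusted over the list alone (adjusted p = 1.56e-07; adjusted p = 0.102 with an estimated correlation). The injury transcription factor Atf3 was at 4.12 (adjusted p = 0.169), Gap43, a growth cone protein, at 1.63 (adjusted p = 0.139) and Sprr1a, which is induced in injured axons, at 3.01 (adjusted p = 0.274). The wildtype levels of Atf3 and Sprr1a are close to background, so the size of their differences is uncertain. Neurofilament and axonal transport genes were higher in 20 of 22 (median 0.22, 1 adjusted over the list alone, adjusted p = 0.00031; adjusted p = 0.497 with an estimated correlation), with the filament subunit Ina at 1.26. Glycolysis genes were higher in 13 of 13 (median 0.24, 0 adjusted over the list alone, adjusted p = 0.00117; adjusted p = 0.497 with an estimated correlation). Heat shock chaperones were higher in 12 of 15 (median 0.13, 2 adjusted over the list alone, adjusted p = 0.00117; adjusted p = 0.413 with an estimated correlation). Synaptic vesicle genes were higher in 14 of 18 (median 0.23, adjusted p = 0.0204; adjusted p = 0.497 with an estimated correlation). Autophagy and lysosome genes were higher in 14 of 20 (median 0.13, adjusted p = 0.0243; adjusted p = 0.241 with an estimated correlation). Astrocyte markers were higher in 10 of 13 (median 0.10, adjusted p = 0.038; adjusted p = 0.497 with an estimated correlation). Each of these 3 lists had 1 member adjusted over the list alone. Oligodendrocyte markers did not pass the test (median -0.12, 3 of 12 higher, adjusted p = 0.228). The actin ratio fell from 46.5 in wildtype to 30.7 in mutants beside these groups too. Wildtype replicate 1 stood apart with a ratio of 56.9. The mean of the neurofilament and axonal transport genes was higher in wildtype replicate 2 (0.38, relative to the wildtype mean) than in every mutant array (0.25 to 0.33). The means of glycolysis (0.26) and synaptic vesicle genes (0.35) in that array also lay within the mutant range.

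In all, 6 genes rose and 1 fell in mutant spinal motor neurons among 10916 tested, and in each of the 7 the 3 arrays of one genotype lay above the 3 of the other. Over all tested genes, 1037 had an unadjusted p under 0.05. The groups did not overlap in 14.3% of genes, against 10% by chance, and 11 of 34 lists passed. Another split of these 6 arrays also passed 11 lists. With the deposited values at a common median 7 genes were higher and 4 lower, so 63.6% in place of 85.7% were higher. Other genes with lower values did not pass, such as Sbsn, a secreted protein of epithelia, at -1.38 (adjusted p = 0.0562) and Ccni, a cyclin, at -1.25 (adjusted p = 0.0603). Other bright probe sets of Ccni gave 0.01 and -0.15, and another of Sbsn gave -0.45. The count was 31, 666 and 4 without wildtype replicates 1, 2 and 3, and 2, 3 and 2 without mutant replicates 1, 2 and 3. The predominance of higher genes did not hold in every alternative, with 347 higher and 319 lower without wildtype replicate 2, and 61 higher and 62 lower with all 18 arrays in one fit. Gfap and Laptm5 passed with each array left out, while Ctss, H2-K1, Ctsz, Grn and Psmd6 did not pass without wildtype replicate 3 (adjusted p between 0.0647 and 0.128) or without any one of the mutant arrays (0.0684 to 0.334). With no mean-variance trend 1 gene passed, and with the actin ratio as a covariate none did (limma, 314 genes at an unadjusted p under 0.05).

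**Figure D1:**
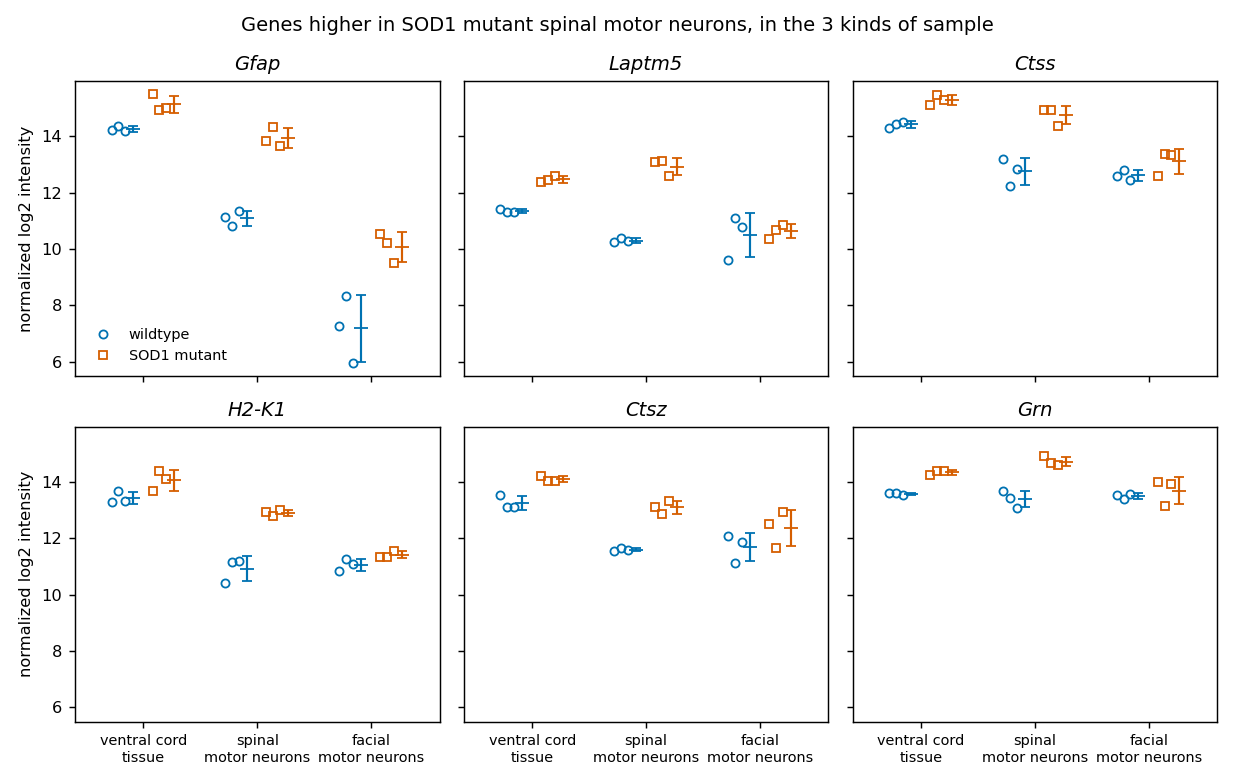
Normalized log2 intensity of the 6 genes that rose in SOD1 mutant spinal motor neurons, in ventral cord tissue, spinal motor neurons and facial motor neurons (circles wildtype, squares SOD1 mutant, 1 point per array, bars mean and SD of 3 arrays). In spinal motor neurons every mutant array lies above every wildtype array, as with Gfap at a mean of 13.95 against 11.10.

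In whole ventral cord tissue of SOD1 mutants, microglial, interferon and reactive glial genes rose. Mpeg1, a pore-forming protein of macrophages, rose by a log2 difference of 1.72 (SE 0.11, n = 3 per group, adjusted p = 0.000383). The interferon-induced genes Ifit3 and Usp18 rose by 1.58 (SE 0.12, adjusted p = 0.0013) and 1.88 (SE 0.19, adjusted p = 0.00348). Timp1, an inhibitor of metalloproteinases made by reactive astrocytes, rose by 1.74 and Cd52 by 1.73. Lgals3, a galectin of activated microglia, rose by 1.56 and Clec7a, a pattern receptor of microglia, by 1.48. These 4 genes had adjusted p between 0.00348 and 0.0167. Among the genes that fell were Sbsn by 1.28 (SE 0.13, adjusted p = 0.00366) and Podxl2, a sialomucin, by 0.95 (SE 0.09, adjusted p = 0.00346). Galc, a lysosomal enzyme of myelin lipid breakdown, fell by 0.83 (SE 0.11, adjusted p = 0.00996) and the axonal motor protein Kif5a fell by 0.31 (SE 0.05, adjusted p = 0.0247).

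By list, microglia markers were higher in mutant tissue in 15 of 15 (median 0.75), with 9 past the threshold and 12 adjusted over the list alone (adjusted p = 6.1e-26; adjusted p = 0.0527 with an estimated correlation). Among them were Tyrobp, a signalling adaptor, at 1.16 and Cd68, a lysosomal protein, at 1.30. Genes of microglial activation were higher in 13 of 13 (median 0.84, 9 past the threshold, 11 adjusted over the list alone, adjusted p = 7.97e-23; adjusted p = 0.0527 with an estimated correlation). Interferon and antigen presentation genes were higher in 14 of 15 (median 0.66, 7 past the threshold, 12 adjusted over the list alone, adjusted p = 7.68e-19; adjusted p = 0.0779 with an estimated correlation). Reactive astrocyte genes were higher in 10 of 11 (median 0.71, 4 past the threshold, 9 adjusted over the list alone, adjusted p = 3.21e-13; adjusted p = 0.0779 with an estimated correlation), and Gfap rose by 0.88 (SE 0.13, adjusted p = 0.0198). Complement genes were higher in 6 of 6 (median 0.72, 2 past the threshold, 4 adjusted over the list alone, adjusted p = 7.19e-07; adjusted p = 0.131 with an estimated correlation).

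Smaller upward shifts passed in tissue for heat shock chaperones (14 of 15 higher, median 0.06, adjusted p = 0.000443), where Hspa1a, an inducible chaperone, rose by 1.29 (adjusted p = 0.0222), and for astrocyte markers (12 of 14, median 0.07, adjusted p = 0.00177). Both were lost at adjusted p = 0.0779 and 0.0947 with an estimated correlation. They also passed for mural and fibroblast genes (8 of 9, median 0.39, adjusted p = 0.00459; adjusted p = 0.263 with an estimated correlation), where the mean of mutant replicate 1 (0.06, relative to the wildtype mean) lay below wildtype replicate 3 (0.20), and ribosomal proteins (32 of 40, median 0.05, adjusted p = 0.0117; adjusted p = 0.11 with an estimated correlation). Autophagy and lysosome genes (11 of 20, median 0.02, adjusted p = 0.0117), apoptosis genes (12 of 13, median 0.10, adjusted p = 0.0138) and axon injury genes (11 of 16, median 0.10, adjusted p = 0.0496) passed as well. These had adjusted p = 0.236, 0.131 and 0.191 with an estimated correlation. Over the list alone 2 heat shock, 2 astrocyte, 3 lysosomal, 1 apoptosis and 1 axon injury genes passed. Of the lists, 5 were lower in mutant tissue, while motor neuron markers did not pass (median -0.01, mean 0.16, adjusted p = 0.247). Voltage-gated channels were lower in 17 of 20 (median -0.12, 1 adjusted over the list alone, adjusted p = 0.000173; adjusted p = 0.0779 with an estimated correlation). Synaptic vesicle genes were lower in 15 of 18 (median -0.11, adjusted p = 0.000443; adjusted p = 0.0779 with an estimated correlation). Of these, 5 members fell and 1 rose adjusted over the list alone. Neurofilament and axonal transport genes were lower in 14 of 22 (median -0.05, 1 past the threshold, 3 adjusted over the list alone, adjusted p = 0.00844; adjusted p = 0.11 with an estimated correlation), and the arrays of the genotypes overlapped in their mean. Calcium buffering genes (9 of 11 lower, median -0.09, adjusted p = 0.0162) and glutamate receptors (11 of 16 lower, median -0.10, adjusted p = 0.0409) had 0 members adjusted over the list alone. They had adjusted p = 0.258 and 0.184 with an estimated correlation.

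In tissue 55 genes rose and 15 fell among 10916 tested, and the groups of all 70 did not overlap. In all, 1083 genes had an unadjusted p under 0.05, and 17 of 38 lists passed. The groups did not overlap in 15.7% of genes, against 10% by chance. With the deposited values at a common median, 36 were higher and 19 lower, so 65.5% in place of 78.6% were higher. The count was 30 and 39 without wildtype replicates 2 and 3, and 119, 32 and 13 without mutant replicates 1, 2 and 3. With all 18 arrays in one fit 4 genes passed, all lower in mutants, and none of the 55 that rose. Of the named genes with a second bright probe set, Cdip1 and Sod1 had one of the opposite sign.

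Gfap, Laptm5, Ctss, Ctsz and Grn rose both in mutant tissue and in mutant spinal motor neurons. These are 5 genes, where independent lists of 6 and 45 genes among the 10053 tested in both would share 0.0269. Of the 45 genes that rose in tissue, 43 were higher in mutant spinal motor neurons, with a median log2 difference of 1.39 there against 0.94 in tissue. Of the 15 that fell, 13 were lower there. Across all genes, which are not independent replicates, the genotype differences of tissue and spinal motor neurons correlated at r = 0.14 (rho 0.01). Those of spinal and facial motor neurons at r = 0.19 (rho 0.22), and those of tissue and facial motor neurons at r = -0.01.

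In facial motor neurons no gene passed the test between genotypes (limma, smallest adjusted p = 0.0872), and 1949 genes had an unadjusted p under 0.05. Among the lowest in mutants, the nucleoside diphosphate kinase Nme2 was at -0.69 (SE 0.08, n = 3 per group, adjusted p = 0.0872), Psmd6 at -1.05 (SE 0.15, adjusted p = 0.0914) and Sbsn at -1.61 (SE 0.23, adjusted p = 0.0914). Higher values were measured for Lonrf1, a ring finger protein, at 1.03 (adjusted p = 0.0914), Ifit3 at 1.91 (adjusted p = 0.114) and Arc, an activity-induced gene, at 1.42 (adjusted p = 0.138). Immediate early genes rose as a list (8 of 9 higher, median 0.58, 3 adjusted over the list alone, adjusted p = 0.0392; adjusted p = 0.692 with an estimated correlation), with Jun, a transcription factor of the stress and injury response, at 0.84. Interferon and antigen presentation genes also rose as a list (9 of 10 higher, median 0.44, 1 adjusted over the list alone, adjusted p = 0.0392; adjusted p = 0.692 with an estimated correlation). Microglia markers did not pass: 5 of 10 were higher, with a median of -0.09 (adjusted p = 0.663). Relative to the wildtype mean, their mean was -1.12, 0.74 and 0.38 in wildtype replicates 1 to 3. In mutant replicates 1 to 3 it was -0.23, 0.03 and -0.02. With that spread in wildtype, these arrays do not exclude a rise in mutants. The reactive astrocyte list had a median of -0.11 and a mean of -0.61 while its test pointed up (adjusted p = 0.912). Gfap, under the brightness filter here and so not tested, was at 7.18 ± 1.19 (SD, n = 3) in wildtype and 10.08 ± 0.54 in mutants.

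The actin ratio of these facial samples was 67.6 ± 7.44 in wildtype and 39.8 ± 17.0 in mutants (SD, n = 3), and mutant replicate 2, at 59.0, stood apart from the other mutant arrays at 33.8 and 26.6. Without that array 380 genes passed the test, and without any other array none did (limma). The groups did not overlap in 24.1% of genes, against 10% by chance. Lists passed in 2 of 35 tests, in 9 without mutant replicate 2, in 1 without wildtype replicate 2, and in 0 without mutant replicate 3.

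**Figure D2:**
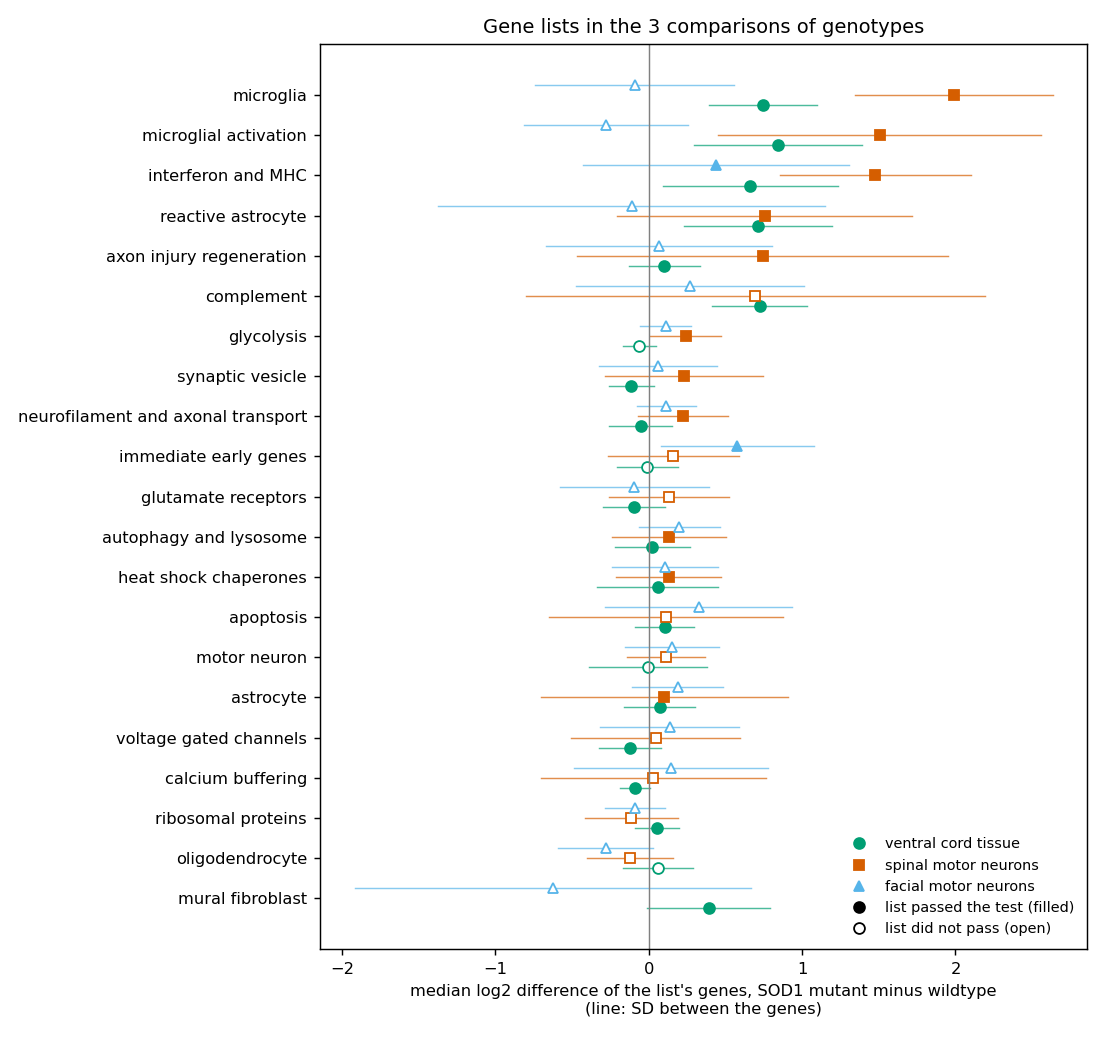
Median log2 difference between SOD1 mutant and wildtype over the tested genes of each list (lines show the SD between genes) in tissue, spinal and facial motor neurons, for lists that passed in at least 1 of these comparisons and the oligodendrocyte and motor neuron markers. Microglia markers had a median of 0.75 in tissue, 1.99 in spinal motor neurons and -0.09 in facial motor neurons.

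The difference between the genotype effects of spinal motor neurons and of tissue was tested as an interaction. It was above 0 for Lpl, Cys1, Gfap, Laptm5 and Sparc and below 0 for Psmd6. Lpl, lipoprotein lipase, passed with the smallest p (log2 difference of the effects 5.18, SE 0.45, n = 3 per group, adjusted p = 0.00024). It was at 11.45 in mutant and 5.42 in wildtype spinal motor neurons, and at 11.68 and 10.84 in tissue. Cys1, a protein of the primary cilium, followed (4.36, SE 0.56, adjusted p = 0.0112). The wildtype motor neuron levels of both are in the range of background, so the size of these differences is uncertain. The Gfap effect was larger in motor neurons by 1.97 (SE 0.28, adjusted p = 0.0189), that of Laptm5 by a factor of 2.83 (SE 0.24 on the log2 scale, adjusted p = 0.0393) and that of Sparc, a matrix protein of astrocytes and vessels, by 0.93 (SE 0.15, adjusted p = 0.0393). For Psmd6 it was -1.07 (SE 0.15, adjusted p = 0.0178), and for Sod1 0.07 (adjusted p = 0.826).

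Of 38 lists, 8 had a more positive and 2 a more negative genotype effect in spinal motor neurons than in tissue. In some the effects had opposite signs. The mean effect was 0.28 in motor neurons and -0.07 in tissue for neurofilament and axonal transport genes, and 0.34 and -0.10 for synaptic vesicle genes. It was 0.27 and -0.02 for glycolysis genes and -0.11 and 0.04 for ribosomal proteins. Microglia markers differed by a median of 1.03 (12 of 13 above 0, 1 past the threshold, 4 adjusted over the list alone, adjusted p = 2.43e-05; adjusted p = 0.552 with an estimated correlation). Genes of microglial activation differed by 0.62 (10 of 12, 1 past the threshold and adjusted over the list alone, adjusted p = 0.00124; adjusted p = 0.53 with an estimated correlation). Neuronal lists differed as well. Neurofilament and axonal transport genes differed by 0.33 (20 of 22, 1 adjusted over the list alone, adjusted p = 0.0003; adjusted p = 0.662 with an estimated correlation). Synaptic vesicle genes differed by 0.37 (15 of 18, 1 adjusted over the list alone, adjusted p = 0.00461; adjusted p = 0.552 with an estimated correlation). Glycolysis genes had a difference above 0 in 13 of 13 (median 0.25, 0 adjusted over the list alone, adjusted p = 0.00252; adjusted p = 0.706 with an estimated correlation). Interferon and antigen presentation genes had a difference above 0 in 12 of 13 (median 0.71, 2 adjusted over the list alone, adjusted p = 0.0191; adjusted p = 0.548 with an estimated correlation). Axon injury genes had a difference above 0 in 12 of 16 (median 0.35, 1 adjusted over the list alone, adjusted p = 0.0332; adjusted p = 0.552 with an estimated correlation). Reactive astrocyte genes had a difference above 0 in 5 of 7 (median 0.41, 1 adjusted over the list alone, adjusted p = 0.0351; adjusted p = 0.53 with an estimated correlation). Ribosomal proteins (28 of 40 below 0, median -0.15, adjusted p = 0.00996) and mural and fibroblast genes (8 of 8 below 0, median -0.81, adjusted p = 0.028) differed the other way, with 0 members adjusted over the list alone. They had adjusted p = 0.706 and 0.548 with an estimated correlation. In spinal motor neurons the ribosomal protein mean of wildtype replicate 2 (-0.35, relative to the wildtype mean) lay below every mutant array (-0.15 to -0.06). The actin ratio was 46.5 and 30.7 in wildtype and mutant motor neurons and 1.63 and 1.64 in tissue.

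This interaction passed for 6 of 10916 genes, 5 above and 1 below 0 (966 at an unadjusted p under 0.05), and 83.3% were above 0. With the deposited values at a common median 4 were above and 0 below, which is 100%. The count was 1, 1 and 1 without wildtype tissue replicates 1, 2 and 3, and 2, 1 and 1 without those of mutant tissue. It was 15 and 877 without wildtype motor neuron replicates 1 and 2, and 2 without mutant motor neuron replicate 1. Lpl passed with each array left out, and the other 5 genes did not pass without wildtype tissue replicate 1, with adjusted p between 0.0623 and 0.173. No gene passed with all 18 arrays in one fit, and 2 with the actin ratio as a covariate.

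The genotype effects of spinal and facial motor neurons differed in no gene past the threshold (limma, smallest adjusted p = 0.219, 987 genes at an unadjusted p under 0.05). The largest values above 0 with small p were those of C1qb, a complement gene of microglia, at 3.75 (SE 0.82), Laptm5 at 2.48 (SE 0.46), Csf1r at 2.29 (SE 0.51) and H2-K1 at 1.63 (SE 0.33), all at adjusted p = 0.219. Below 0 was Nudt12, a nucleotide hydrolase, at -1.43 (SE 0.29, adjusted p = 0.219). Microglia markers differed as a list, with a more positive effect in spinal motor neurons in 11 of 11 (median 2.29, 7 adjusted over the list alone, adjusted p = 1.54e-10; adjusted p = 0.282 with an estimated correlation). Genes of microglial activation did so in 9 of 10 (median 1.08, 4 adjusted over the list alone, adjusted p = 7.41e-06), and this held at adjusted p = 0.026 with an estimated correlation. Axon injury genes had a difference above 0 in 14 of 16 (median 0.65, 3 adjusted over the list alone, adjusted p = 0.00124; adjusted p = 0.282 with an estimated correlation). Interferon and antigen presentation genes had a difference above 0 in 8 of 9 (0.45, 1 adjusted over the list alone, adjusted p = 0.0253; adjusted p = 0.486 with an estimated correlation). Glycolysis genes had a difference above 0 in 12 of 13 (0.17, 0 adjusted over the list alone, adjusted p = 0.046; adjusted p = 0.859 with an estimated correlation). Over the microglia markers tested in facial samples, the wildtype facial arrays lay between -1.12 and 0.74 relative to their mean. The actin ratio was 46.5 and 30.7 in wildtype and mutant spinal and 67.6 and 39.8 in wildtype and mutant facial samples. The number of genes was 2 and 3 without wildtype spinal replicates 1 and 2, 1 without wildtype facial replicate 1 or 2 or mutant facial replicate 1, and 6 without both replicate 1 wildtype arrays. The number of lists, 5 of 35, was 3 without mutant spinal replicate 3 or mutant facial replicate 2 and 8 without wildtype facial replicate 1.

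Wildtype spinal motor neuron samples held more of the transcripts of motor neurons and less of those of glia than the tissue around them. Chodl, a surface protein of fast motor neurons, was higher by 3.98 (SE 0.14, n = 3 per group, adjusted p = 1.35e-06). Mnx1 and Isl1, homeobox factors of motor neuron identity, were higher by 4.43 (SE 0.32) and 4.40 (SE 0.39). Prph, the filament peripherin, was higher by 3.55 (SE 0.22) and Mmp9, a metalloproteinase of fast motor neurons, by 3.94 (SE 0.27). These 4 genes had adjusted p between 7e-06 and 3.45e-05. The chaperone genes Hspb8 and Bag3 were higher by 3.14 (SE 0.14) and 3.47 (SE 0.27). Genes below tissue included Fmod, a matrix proteoglycan, at -8.18 (SE 0.42, adjusted p = 3.57e-06), Igf2, a growth factor of meninges and vessels, at -7.47 (SE 0.32, adjusted p = 1.89e-06). The neuropeptide genes Tac2 and Tac1 were at -6.98 and -6.28. In the motor neuron samples these 4 genes were under 8.79 and close to background, so the size of their differences is uncertain. The astrocyte gene Agt was at -5.35, Gfap at -3.17 and the myelin gene Mag at -4.43. The transmitter genes of interneurons Slc17a6 and Gad1 were at -4.58 and -3.49.

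By list, motor neuron markers were higher in these cells in 16 of 17 (median 1.86, 14 past the threshold and 14 adjusted over the list alone, adjusted p = 5.82e-05; adjusted p = 0.395 with an estimated correlation). Heat shock chaperones were higher in 12 of 15 (median 0.77, 10 higher and 1 lower past the threshold and adjusted over the list alone, adjusted p = 0.0332; adjusted p = 0.398 with an estimated correlation). Astrocyte markers were lower in 14 of 14 (median -2.76, 12 past the threshold, 14 adjusted over the list alone, adjusted p = 3.82e-09; adjusted p = 0.395 with an estimated correlation). Oligodendrocyte markers were lower in 12 of 12 (median -2.55, 12 past the threshold and 12 adjusted over the list alone, adjusted p = 1.2e-08; adjusted p = 0.395 with an estimated correlation). Microglia markers were lower in 13 of 13 (median -1.66, 8 past the threshold, 11 adjusted over the list alone, adjusted p = 0.000305; adjusted p = 0.439 with an estimated correlation). Mural and fibroblast (median -2.91, 7 of 8 past the threshold, adjusted p = 8.41e-05) and inhibitory interneuron markers (-3.08, 4 of 4, adjusted p = 0.00357) were lower. They had adjusted p = 0.395 and 0.398 with an estimated correlation. Excitatory interneuron (-5.43, 3 of 4, adjusted p = 0.00661), oligodendrocyte precursor (-2.14, 5 of 7, adjusted p = 0.00661) and endothelial markers (-2.38, 5 of 7 lower and 1 higher, adjusted p = 0.0202) were lower too. All 3 had adjusted p = 0.398 with an estimated correlation, and in these 5 lists as many genes passed adjusted over the list alone. ER stress genes (median -0.48, 3 up and 11 down, adjusted p = 0.00661) and genes of microglial activation (-1.60, 1 up and 6 down, adjusted p = 0.0113) had adjusted p = 0.395 with an estimated correlation. Voltage-gated channels (-0.85, 1 up and 10 down, adjusted p = 0.0113) and synaptic vesicle genes (-0.66, 4 up and 10 down, adjusted p = 0.0176) had adjusted p = 0.398 and 0.49 with an estimated correlation. Interferon and antigen presentation genes (-1.24, 1 up and 4 down, adjusted p = 0.0393) and ribosomal proteins (-0.25, 5 up and 17 down, adjusted p = 0.00869) had adjusted p = 0.395 and 0.662 with an estimated correlation. These counts were the same adjusted over the list alone, except 11 down for synaptic vesicle genes. The reactive astrocyte list had a median of 0.76 and a mean of -0.91, and did not pass (adjusted p = 0.592).

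In this comparison 3880 genes were higher and 2524 lower past the threshold among 10916 tested, 6338 of these 6404 without overlap between groups. The median over all genes was 0.22. The groups did not overlap in 67.0% of genes, against 10% by chance, and 16 of 37 lists passed. With the deposited values at a common median the median over all genes was 0.69, and 5514 genes were higher and 1499 lower, so 78.6% in place of 60.6% were higher. Ribosomal proteins then had a median of 1.05 in place of -0.25 (adjusted p = 0.1), so differences count relative to the median over all genes. The actin ratio was 46.5 in the cells and 1.63 in tissue, it follows the kind of sample, and as a covariate it left 252 genes. Some directions turned with it, as for Isl1 at -4.43, Igf2 at 1.92 and the oligodendrocyte markers at a median of 0.68, none past the threshold (adjusted p = 0.666, 0.778 and 0.88). Of 75 named genes with a second bright probe set, 21 had one of the opposite sign, Hspb8 among them.

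Homeobox genes differed between wildtype spinal and facial motor neurons. For each one named here the level in the lower group is under 8.79 and close to background, so the size of its difference is uncertain. Mnx1 was higher in spinal motor neurons by 7.08 (SE 0.60, n = 3 per group, adjusted p = 0.000809), at 12.25 against 5.17. Hoxb5 was higher by 6.92 (SE 0.56, adjusted p = 0.000735) and Hoxc8 by 6.05 (SE 0.33, adjusted p = 5.9e-05). Hoxd9 was higher by 5.87 (SE 0.43, adjusted p = 0.000461) and Hoxc10 by 5.10 (SE 0.29, adjusted p = 6.33e-05). Hox genes give positions along the body axis their identity. Shox2, a homeobox gene expressed in the hindbrain, was higher in facial motor neurons, at 14.34 against 7.37 (log2 difference -6.97, SE 0.35, adjusted p = 5.9e-05). Tbx20, a T-box factor of hindbrain motor neurons, was at -3.65 (SE 0.50, adjusted p = 0.00691), and Htr3a, a serotonin receptor subunit, at -2.79 (SE 0.46, adjusted p = 0.0149). The calcium-binding protein genes Calb2, Calb1 and Pvalb were higher in spinal samples by 4.25 (SE 0.35, adjusted p = 0.000735), 4.18 (SE 0.76, adjusted p = 0.0224) and 2.88 (SE 0.40, adjusted p = 0.00749). Slc32a1 and Slc6a5, transporters of inhibitory neurons, were higher by 2.91 (SE 0.43, adjusted p = 0.00932) and 2.88 (SE 0.38, adjusted p = 0.00625), and Gfap was higher too (adjusted p = 0.0126), at 11.10 against 7.18. The lower levels of Gfap, Tbx20, Calb1 and Slc32a1 are also under 8.79, so the size of these differences is uncertain.

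Of the 18 Hox genes of paralog groups 5 to 11 on the array, 7 passed the brightness filter, which keeps those bright in spinal samples, since all were under 8.79 in the facial ones. These 7 were higher in spinal motor neurons (median 5.77, 7 past the threshold and adjusted over the list alone, adjusted p = 9.04e-14), and this held at adjusted p = 0.0431 with an estimated correlation. Of the 11 not tested, 9 were higher (up to 4.99) and Hoxb7 (-0.57) and Hoxd11 (-1.13) lower, with a median of 3.26. Cholesterol synthesis genes were higher in 14 of 17 (median 0.37, 2 past the threshold, 7 adjusted over the list alone, adjusted p = 0.00186; adjusted p = 0.301 with an estimated correlation). Idi1, an isomerase of the pathway, was at 0.61. Ribosomal proteins were lower in 34 of 40 (median -0.21, 1 past the threshold, 0 adjusted over the list alone, adjusted p = 0.00186; adjusted p = 0.859 with an estimated correlation). Mural and fibroblast genes were lower in 6 of 7 (median -2.12, 2 past the threshold, 3 adjusted over the list alone, adjusted p = 0.0197; adjusted p = 0.859 with an estimated correlation), such as the collagen Col3a1 at -3.39 and Lum, a proteoglycan, at -3.38, both under 8.79 in spinal samples. Over the members tested between genotypes in facial samples, wildtype replicate 1 was at -1.89 relative to the wildtype mean. Wildtype replicates 2 and 3 were at 1.13 and 0.77, so the facial arrays differed widely among themselves. The actin ratio was 46.5 ± 9.06 in the spinal and 67.6 ± 7.44 in the facial samples (SD, n = 3).

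Between the sites 233 genes were higher and 199 lower in spinal motor neurons among 10916 tested, all 432 without overlap between groups. In all, 2348 genes were at an unadjusted p under 0.05, and 4 of 35 lists passed. Other splits of these 6 arrays passed a median of 5 lists and up to 7. The groups did not overlap in 28.5% of genes, against 10% by chance. Of 20 named genes with a second bright probe set, 7 had one of the opposite sign. The count was 685 and 74 without wildtype spinal replicates 2 and 3, and 216, 112 and 66 without wildtype facial replicates 1, 2 and 3, and the number of lists went from 2 without spinal replicate 2 to 6 without spinal replicate 1. With the actin ratio as a covariate 4 genes passed, Shox2, Hoxc8 and Hoxc10 among them (adjusted p = 0.01, 0.0193 and 0.0217). Hoxc8, Hoxc10 and Shox2 passed under every alternative that was run.

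**Figure D3:**
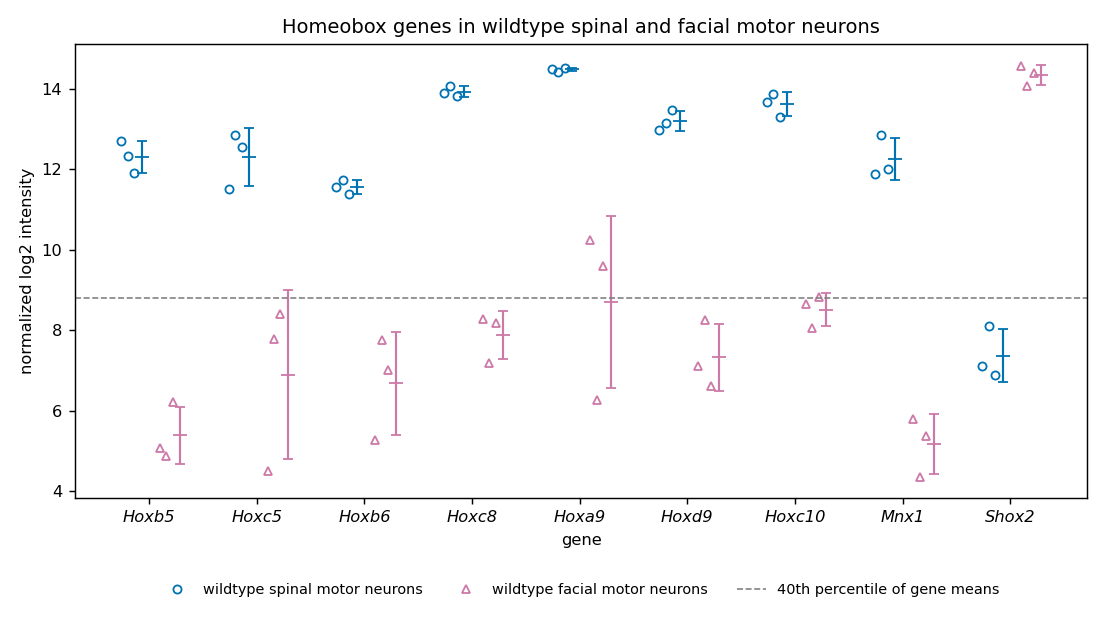
Normalized log2 intensity of the 7 tested Hox genes of paralog groups 5 to 11 and of Mnx1 and Shox2 in wildtype spinal (circles) and facial (triangles) motor neurons, 1 point per array, with mean and SD of 3 arrays. The dashed line is the 40th percentile of gene means over the 18 arrays, 8.79, and spinal Mnx1 lies above it at a mean of 12.25 while facial Mnx1 lies below it at 5.17.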

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

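The 4 tests of why glial and immune genes were higher in mutant spinal motor neuron samples were chosen only after that result was seen. The interactions and the splits of the samples were chosen earlier.

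The genotype effect of 6 genes differed between spinal motor neurons and tissue by a test of the difference itself. The log2 difference of the effects was 5.18 for Lpl, 4.36 for Cys1, 1.97 for Gfap, 1.502 for Laptm5, 0.93 for Sparc and -1.07 for Psmd6. The wildtype motor neuron levels of Lpl and Cys1 were close to background, so the size of their differences is uncertain. Of the gene lists, microglia markers (adjusted p = 2.43e-05), neurofilament and axonal transport genes (0.000300), microglial activation (0.00124), glycolysis (0.00252), synaptic vesicle (0.00461), ribosomal protein (0.00996), interferon and antigen presentation (0.0191), mural and fibroblast (0.028), axon injury (0.0332) and reactive astrocyte genes (0.0351) differed by the same test. None of these 10 lists passed with an estimated correlation, where the smallest adjusted p = 0.53. Between spinal and facial motor neurons it was microglia markers (adjusted p = 1.54e-10), microglial activation (7.41e-06), axon injury (0.00124), interferon and antigen presentation (0.0253) and glycolysis genes (0.046). With an estimated correlation only microglial activation passed (adjusted p = 0.026), and microglia markers and axon injury genes were at adjusted p = 0.282, interferon at 0.486 and glycolysis at 0.859.

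Other splits of the samples do not exclude chance for the interaction with tissue or for the lists of the other one. For the interaction with tissue, 7 of 100 drawn splits gave as many as the real 6 genes, and the highest of the others gave 87. A split with so many more genes points to a structure of the samples beside the groups, which was not identified. Without wildtype spinal motor neurons replicate 2 this interaction passed for 877 genes, and whether that array is part of the structure was not tested. As many as the real 10 lists passed in 18 of 100 splits, with 15 in the highest of the others. For the interaction with facial motor neurons, the real count was 0 genes (limma, 987 at an unadjusted p under 0.05), which all 100 splits reach whatever the data, so their count decides nothing, and the highest of the others was 2. As many as the real 5 lists passed in 36 of 100, and the highest of the others had 14.

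Astrocyte and microglia genes, Gfap and Laptm5 first, were higher in mutant spinal motor neuron samples, and a candidate explanation is more surrounding tissue of every kind in those samples. The median share of tissue that the rise of the microglia markers would need, 41.6%, would raise the oligodendrocyte markers, which include abundant myelin genes, by a median of 1.81. They were at -0.12 (SD between genes 0.28), with 12 of 12 below the prediction, which argues against it. An unchanged share of tissue that itself differs between genotypes needs a genotype effect in motor neuron samples no larger than in tissue. For the 6 genes that rose, chosen by their difference in motor neurons, the effect on their mean per array was larger by 1.198 (SE 0.087, n = 3 per group, 95% interval from 0.998). With each of 12 arrays left out it was between 1.16 and 1.27. Choosing the genes by their motor neuron difference in itself pushes this value above 0, also with arrays left out. It therefore does not decide the question for these genes. All 6 interactions were above 0, at 1.97 (SE 0.28) for Gfap, 1.502 (SE 0.24) for Laptm5, 1.36 (SE 0.32) for H2-K1, 1.13 (SE 0.30) for Ctss, 0.66 (SE 0.22) for Ctsz and 0.57 (SE 0.21) for Grn. The last 4 did not pass over all genes (smallest adjusted p = 0.348). With an array left out Gfap did not pass in 6 and Laptm5 in 9 of 12, while their interactions stayed between 1.77 and 2.14 and between 1.41 and 1.67. This explanation also stays open for the microglia markers, a list fixed before the data were examined. Of these markers, 12 of 13 were above 0, but the effect on their mean was larger by 0.99 with an SE of 0.57 (95% interval from -0.33).

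RNA quality differing between genotypes stays open for those 6 genes and could contribute. The actin ratio was between 40.9 and 56.9 in wildtype and between 25.3 and 39.1 in mutant spinal motor neurons. The Gapdh ratio overlapped between genotypes, at 49.7, 19.1 and 28.6 in wildtype and 20.5, 21.2 and 21.7 in mutants. It was not used as a covariate. With the actin ratio as a covariate the median log2 difference of the 6 genes was 2.17 in place of 1.99, and their median SE was 0.38 in place of 0.24. The calls ended, with a smallest adjusted p = 0.0924. The SE rose and the covariate takes a degree of freedom. The estimates of H2-K1 and Ctsz fell from 1.99 to 1.59 and from 1.502 to 1.43, while those of Gfap, Laptm5 and Grn rose to 2.87, 2.77 and 1.73 from 2.85, 2.63 and 1.33, and that of Ctss to 2.604. An effect of the genotype on glia close to or picked with the motor neurons also stays open and was not tested.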

How the results depend on the processing

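Genes near background and groups of 3 limit the precision of these results, and 523 named results were recomputed under the alternatives, 9496 values in all, of which 67 had the opposite sign. The actin ratio as a covariate and both replicate 1 wildtype motor neuron arrays left out together were chosen after seeing the data. Counts of genes are given in the order used in the report, and the cause was not tested unless it is named. With the deposited values at a common median 11 genes passed between genotypes in spinal motor neurons, where 7 did otherwise. A pseudocount of 64 and no filter each gave 13 there, and a filter at the 60th percentile gave 1 in facial motor neurons. With every probe set tested, 12889 passed between motor neurons and tissue, since more features were tested, and 1 in the interaction with facial motor neurons. With no mean-variance trend the counts were 1 in spinal motor neurons, 31 in tissue, 2 in the interaction with tissue, 1 in that with facial motor neurons and 196 between the sites. With all 18 arrays in the fit they were 123 in spinal motor neurons, 4 in tissue, 285 in facial motor neurons, 0 in the interaction with tissue (limma), 26 in that with facial motor neurons and 1834 between the sites. With array weights they were 134, 145 and 732 in spinal motor neurons, tissue and facial motor neurons, 96 in the interaction with tissue and 3222 between the sites.

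The rule for a pairing by replicate number was not met, since in 0 of 11 pairs of groups did every same-number correlation exceed 0.1 (they were between -0.27 and 0.30). Between genotypes they were 0.30, 0.07 and 0.08 in tissue, 0.02, 0.10 and 0.05 in spinal and 0.12, 0.12 and 0.03 in facial motor neurons. The rule cannot exclude that samples with the same replicate number share an animal or a run. As a block the replicate numbers gave 16, 137 and 1 genes in spinal motor neurons, tissue and facial motor neurons, 2 in the interaction with tissue, 233 between the sites, and 4 lists in facial motor neurons. With the actin 3' to 5' ratio as a covariate the counts were 0 in spinal motor neurons (limma, 314 at an unadjusted p under 0.05), 144 in tissue, 2 in the interaction with tissue, 252 between motor neurons and tissue and 4 between the sites. The lists were then 1 in facial motor neurons and 9 between motor neurons and tissue. With both wildtype motor neuron arrays that stand apart left out, 6 genes passed in the interaction with facial motor neurons. With an estimated inter-gene correlation 0 lists passed in the 3 genotype comparisons, in the interaction with tissue and between motor neurons and tissue, and 1 in each of the other comparisons (camera in limma). With each array left out in turn, the genes were 2 to 666 in spinal motor neurons, 13 to 119 in tissue, 0 to 380 in facial motor neurons, 1 to 877 and 0 to 3 in the interactions with tissue and facial motor neurons, and 66 to 685 between the sites. The lists were 0 to 9 in facial motor neurons, 3 to 8 in the interaction with facial motor neurons and 2 to 6 between the sites. S1pr3 in the interaction with tissue was between -0.66 and 1.67, and -0.10 without mutant spinal motor neurons replicate 1.

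Values of the opposite sign with the deposited values at a common median were, in the interaction with tissue, Ifit3 at 0.022 and Sod1 at -0.16. Between motor neurons and tissue they were the ribosomal protein list at 1.05, Rpl4 at 0.26, Kif5b at 0.24, Kcnk1 at 0.27, Pfkm at 0.31 and Pgam1 at 0.82 (adjusted p = 0.000388). With the actin 3' to 5' ratio as a covariate they were Map1b at -0.13, Vamp1 at -0.0043 and Sv2c at -0.13 between genotypes in spinal motor neurons, Oasl2 at -0.076 in facial motor neurons, and the ribosomal protein list at 0.072 and Grm7 at 0.016 between the sites. In the comparison of motor neurons with tissue, where that ratio follows the kind of sample, 51 results took the opposite sign, with a smallest adjusted p = 0.0603 over its genes and lists. The lists were oligodendrocyte at 0.68, oligodendrocyte precursor at 3.30 and synaptic vesicle genes at 1.23. Genes above 0 were Igf2 at 1.92, Cd9 0.40, Gabra3 0.28, Mal 0.77, Fdps 6.24, Serpinb1b 9.89, Ncald 1.45, Gria2 2.03, Sqstm1 2.86, Psmc5 0.89, Rgs5 0.28, Cdkn1c 10.26, Olig1 2.24, Baiap3 0.95, Hoxd8 2.62, Hpca 5.70, Mapk8ip1 12.61, H2-K1 5.48 and Kif5b 0.014. So were Pdia6 at 0.68, Pdia4 0.73, Gpr17 8.86, U2af1 6.18, Grm3 3.15, Grik5 12.13, Ccnd2 13.10, Tek 9.29, Olig2 6.14, Pfkm 7.44 and Pgam1 2.74. Genes below 0 were Amhr2 at -0.78, Ndufa5 -0.84, Psmb3 -2.05, Txn1 -0.92, Dnah2 -0.40, Isl1 -4.43, Cfi -3.76, Ret -1.96, Ndufb3 -2.66, Ifi27 -1.19, Jun -2.14, Bad -1.74, Gclm -0.22, Casp9 -4.94, Tnfrsf1a -7.98, Gabrg1 -7.17, Gabra2 -2.45 and Tgfb2 -4.36. With the probe set used for each gene, results not named here kept their sign under the alternatives that were run. Other probe sets of a gene were not compared in this way, and some had the opposite sign, as for Cdip1 and Hspb8.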

Other observations

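The tests of other probe sets of the genes shared by the 3 kinds of sample, and both tests of facial motor neurons, were chosen only after the results were seen. Motor neuron markers did not pass between genotypes: their median log2 difference was 0.11 in spinal motor neurons (12 of 18 higher, adjusted p = 0.261), 0.15 in facial motor neurons (14 of 17, adjusted p = 0.0808) and -0.01 in tissue (7 of 14, mean 0.16, adjusted p = 0.247). ER stress genes had medians of 0.11, 0.05 and 0.05 in the same order (adjusted p = 0.261, 0.885 and 0.288), and respiratory chain genes -0.05, -0.02 and -0.02 (adjusted p = 0.329, 0.298 and 0.146). Proteasome genes had medians of -0.05, -0.05 and 0.01 (adjusted p = 0.0725, 0.112 and 0.807). Genes linked to amyotrophic lateral sclerosis had medians of 0.17, -0.01 and -0.01 (adjusted p = 0.128, 0.663 and 0.732). The test pointed down for ER stress genes in facial motor neurons and up for genes linked to the disease in tissue, against the sign of the median.

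In all 3 kinds of sample, 32 of the 9799 genes tested in each had the same direction at an unadjusted p under 0.05, among them Sbsn, Ccni and Ep400, which were lower in mutants, and Ifit3 and Sod1, which were higher. Of these, 20 were lower and 12 higher, where 4.05 would be expected of independent comparisons. Relabellings of the arrays do not decide on chance agreement of unrelated differences, although 1 of 100, the real one, gave as many, and the highest of the others gave 11. Other splits also had fewer genes at an unadjusted p under 0.05 within each kind. Their median was 247 in spinal motor neurons, 310 in tissue and 303 in facial motor neurons, against 1037, 1083 and 1949. Fewer shared genes follow from that alone. A single chromosomal segment that differs between the genotypes is argued against as the whole cause. Of the genes, 4 pairs lay within 25 tested genes of each other. The upper end of the central range of random draws of as many genes was 6. At most 2 of the genes lay within one stretch of 25 tested genes. Several segments need not raise these counts, so they stay open. The distance of 25 tested genes was set after the pattern had been seen.

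A difference seen by 1 probe set of the gene only may explain part of these 32 genes, and the values it needs are there. For 21 of them 36 other probe sets passed the filter, with a median log2 difference of 0.066 (SD 0.46) in the direction of the gene, where the probe sets used for the same genes had 0.65. Among the genes named, other probe sets of Ccni gave 0.01, 0.27 and 0.50, and -0.15, 0.03 and 0.08, in spinal motor neurons, tissue and facial motor neurons. Those of Ep400 gave -0.24, -0.26 and 0.11, and -0.29, -0.29 and 1.06. For Sbsn the other probe set kept the direction (-0.45, -0.38 and -0.82), and those of Sod1 are given above. Of the 36, 9 had the same direction in all 3 kinds. A sequence difference between the strains of the genotypes at those probes, or transcripts that differ in part, would both do this, and the data do not separate them. An effect of the genotype itself stays open and was not tested.

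In facial motor neurons no gene passed between genotypes (limma) although 1949 had an unadjusted p under 0.05, and 1 array that stands apart may be the source. Without mutant replicate 2, 380 genes passed, and leaving 1 array out of the other splits of the same 6 arrays gave at most 242. The values this explanation needs are there, although by its mean correlation with its group (0.938) that array was not apart from the other mutant arrays (0.942 and 0.943), and wildtype replicate 1 was lowest (0.924), without which no gene passed (limma, 1899 at an unadjusted p under 0.05). RNA quality differing between genotypes stays open, and these data cannot tell it apart from the array that stands apart. The actin ratio of mutant replicate 2, 59.0, was close to those of wildtype (59.7 to 74.4), while the other mutant arrays were at 33.8 and 26.6. Leaving mutant replicate 2 out thus also widens the difference in this ratio between genotypes. With the actin ratio as a covariate 901 genes had an unadjusted p under 0.05, 468 of them also without it, and the highest of the other splits of the 6 arrays gave 1272 with the covariate. An effect of the genotype that is smaller in that array stays open and was not tested.

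Between 3 and 3 arrays there are 10 splits, too few for a share under 0.05. At an unadjusted p under 0.05 the highest of the other splits gave 1284 genes in spinal motor neurons, where the real split gave 1037, 1367 in tissue, where it gave 1083, and 1339 in facial motor neurons, where it gave 1949. Between genotypes in spinal motor neurons 1 split gave as many as the real 7 genes, with 0 in the highest of the others, and 2 as many as the real 11 lists, with 11. In tissue 1 gave as many as 70 genes, with 0 in the others, and 1 as many as 17 lists, with 10 in the highest other. In facial motor neurons 10 gave as many as 0 genes, with 0 in the others, and 8 as many as 2 lists, with 7 in the highest other. Between motor neurons and tissue 1 gave as many as 6404 genes, with 0 in the others, and 1 as many as 16 lists, with 11. Between the sites 1 gave as many as 432 genes, with 1 in the highest other, and 8 as many as 4 lists, with 7.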
